A study of Triticum aestivum with 14 samples.

How the data were processed

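RNA was extracted with Trizol, and libraries were made from RNA with an integrity number above 7.0, per the labels. The deposited table gave, for each of 14 libraries and 100591 genes, the authors' raw counts (whole numbers of reads or fragments per gene) and the authors' FPKM values (fragments scaled to gene-model length and to library size). The processing notes name Bowtie 0.12.2 and the genome build mm8. That is a mouse build and cannot hold wheat genes, so the aligner, the build and the annotation behind the wheat values are not given in the sources used here. Gene positions are those of the deposited table, on a build that is not given. None of the table's gene IDs matched the newer wheat annotation at hand (0 genes), which was therefore not used.

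Names and descriptions came from the table and cover 15248 genes (15.2%), gene ontology text covers 69.4% and pathway assignments 29.2%. The groups were taken from the sample titles. The label N50 was left unexplained. The replicate numbers were not taken to pair samples across groups, which the sample titles do not settle. No replicate block was used for the values reported first.

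Before the data were examined, the comparisons, tests, thresholds, gene lists, alternatives and the rule for naming genes were fixed. The fixed plan expected FPKM and named limma on log2(FPKM + 1) for every comparison, with edgeR for F5 against F1 should the table hold counts. Because it holds counts, edgeR was used for all 4 comparisons. For the organ comparisons that is a departure from the plan, made after the data were seen, and limma on log2(FPKM + 1), their planned test, is given as an alternative. The DESeq2 Wald test was added after the data were seen.

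Counts were scaled by the trimmed mean of M-values (TMM), genes with too few counts were removed with filterByExpr, and robust quasi-likelihood models were fitted in edgeR 4.0.16 under R 4.3.3. F1 and F5 were fitted by themselves, and Lemma, Anther and Ovary in 1 fit, so that Lemma with its 2 libraries shared an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Tests were two-sided. The SE of a log2 fold change was its size divided by the square root of the F statistic. A gene was organ-enriched when it was called higher in that organ than in each of the other two. Group values are means and SDs of deposited FPKM. Where a group had no counts for a gene, the fold was bounded by setting that group's total to 3 counts, and such bounds cover counting error only. Total counts of 75016595 to 105526441 per library leave counting error small next to the spread between libraries for abundant genes: within groups the chi-square per degree of freedom was 16.2 to 112.

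Of 53 gene lists, matched as text patterns to names and descriptions or, where a gene had neither, to its ontology terms, 43 had at least 5 tested members and were tested. After the annotation text was seen and before any test, 14 lists were added because some patterns had matched more or less than their names say. The hexokinase or fructokinase list holds mostly 6-phosphofructokinases, and the pollen list holds many genes for recognition of pollen. The tapetum and exine list is dominated by strictosidine synthase activity, and the heat shock protein list by ontology terms for binding such proteins. The organelle-encoded or ribosomal RNA list is mixed. Lists and 137 pathways were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of one kind in one comparison, and beside it with an estimated correlation and with fry. Camera asks whether a list changed more than other genes, and fry whether it changed at all, so that many lists pass fry where many genes change. Medians were also computed with genes at 0 in one group set to their bound, and are given where they differ.

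The naming rule took, for F5 against F1, the 8 described genes that rose and the 8 that fell most among genes called, with at least 10 FPKM in the higher group and no overlap between the libraries, and up to 2 called members of each list. For each organ it took the 8 described organ-enriched genes with the largest smaller fold change and members of passing lists. The rule also said that at most 2 IDs that rose and 2 that fell would be printed where under 20% of tested genes had a name or description. The share was 14.4% for the florets and 14.1% for the organs. After that share was seen, the limit was applied only to genes with neither a name nor a description, which is a departure from the plan.

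The tests were tried on simulated counts with known changes. In F5 against F1, edgeR recovered 34 of 100 genes changed 4-fold and 0 of 100 changed 2-fold, and called 2 unchanged genes of 68553 tested. In Anther against Lemma it recovered 48 and 1, with 4 unchanged genes called, and in Anther against Ovary 55 and 5, with 3. Recovery was counted at an adjusted p under 0.05 without a minimum fold, and changes near 2-fold were largely missed. Only these genes were changed in the simulation, a far smaller share than the 24.1% called in F5 against F1. That makes the adjustment stricter than in the data, so these recoveries do not carry over to the data. Camera called a simulated list of 40 changed genes (adjusted p = 3.68e-44) and 0 of 40 lists without a change. The genes were simulated independently of one another, so this does not show how camera behaves where the members of a list are correlated.

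The alternatives were another pseudocount (limma on log2(FPKM + 0.1)), no filter on low values, at least 5 FPKM, median-of-ratios scaling, quantile normalization of log2(FPKM + 1), a replicate block, all 14 libraries in 1 fit, no minimum fold, camera with an estimated correlation and leaving out each library in turn. DESeq2 1.42.0 gave the Wald test. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.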

Results

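Transcript abundance was measured by bulk RNA-seq in 14 wheat (Triticum aestivum) libraries from untreated central spikelets sampled 21 days after the terminal spikelet stage. The labels form 5 groups: F1 (n = 3), F5 (n = 3), Lemma (n = 2), Anther (n = 3) and Ovary (n = 3). The stated design compares fertile with abortive florets and, separately, the lemma, anther and ovary of a fertile floret. F1 and F5 were taken as the floret samples, and the labels do not say which of them was fertile. Total counts per library ranged from 75016595 to 79847721 in F1, 100415586 to 105526441 in F5, 98099271 to 100117298 in Lemma, 76441070 to 96159764 in Anther and 80349973 to 103924952 in Ovary. Nothing in the labels says that replicates were separate plants, so every p-value measures the spread between these samples only, and that spread could be technical in part.

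The 5 groups separated in a principal component analysis of 68319 genes, with Anther at one end of the first component and F5 and Lemma at the other. Correlations were computed across genes, which are not independent replicates. F5 resembled Lemma most closely (mean r = 0.83), whereas F1 lay about equally close to Ovary (mean r = 0.783), F5 (mean r = 0.783) and Lemma (mean r = 0.776). Anther was nearer to F1 (mean r = 0.594) than to F5 (mean r = 0.415). The F1 libraries were the least uniform: F1 replicate 1 correlated with the other two at 0.899 and 0.886, while every other pair within a group lay between 0.937 and 0.972.

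**Figure D1:**
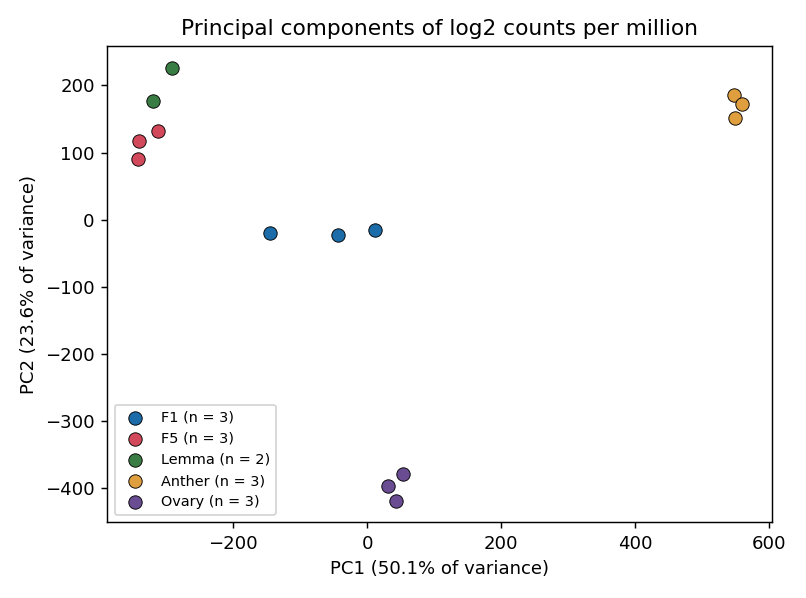
Principal components 1 (50.1% of variance) and 2 (23.6%) of the log2 CPM of 68319 genes; each point is one library and colours mark the 5 groups. The F1 libraries lie between -144.6 and 11.64 on component 1, the F5 libraries between -342.7 and -312.7, and the Anther libraries between 547.3 and 559.9.

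The comparison of F5 with F1 addresses how fertile and abortive florets of central spikelets differ in transcription. Any other difference between F1 and F5, such as position or stage of development, cannot be told apart from fertility here. By camera with its preset correlation, core histone and DNA replication genes were called lower in F5 as lists, and lignin synthesis, photosystem, Calvin cycle and cuticle genes higher; none of these calls held with an estimated correlation (adjusted p from 0.0927 to 0.65). Of 441 tested core histone genes, 398 were lower in F5 and 0 were higher (406 lower when adjusted over the list alone), with a median log2 fold change of -4.47. Of 79 lignin synthesis genes, 50 were higher and 1 was lower (52 and 1 adjusted over the list alone), with a median of 1.89. Individual genes reached larger changes: the NAC domain transcription factor gene TraesCS5B02G142100 rose from 0.121 ± 0.129 FPKM in F1 to 36.7 ± 16.5 in F5 (SD, n = 3), and the sucrose:fructan 6-fructosyltransferase gene TraesCS4A02G485400, whose product builds fructan from sucrose, fell from 81.0 ± 6.73 to 1.93 ± 0.578 FPKM. In all, 16958 of 70221 tested genes changed (24.1%), 7332 higher and 9626 lower in F5, of which 2917 and 5606 changed at least 4-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold).

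That total depended on the test and filter, at 8592 genes with limma on log2(FPKM + 1), 8000 after quantile normalization and 5244 among genes with at least 5 FPKM, and on the other side 20594 with the DESeq2 Wald test. The excess of lower genes did too: 2656 were higher and 2588 lower among genes with at least 5 FPKM, and 4178 and 3822 after quantile normalization. No gene list below kept its call in F5 against F1 when camera estimated the correlation between genes (0 of 43 lists past the threshold, 9 at an unadjusted p under 0.05). Fry, which asks whether a list changed at all and not whether it changed beyond other genes, put 24 of the 43 past it and so does not offset that loss.

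The core histone, DNA replication and meiosis lists were called lower in F5, calls lost with an estimated correlation (adjusted p = 0.152, 0.235 and 0.152). Among the organs, each of these lists had its highest median level in Ovary and its lowest in Lemma. Whether other proportions of organs in F5 account for the DNA replication and meiosis lists was not tested. Cyclin or cyclin-dependent kinase genes did not pass as a list, with 3 higher and 5 lower of 29 (5 and 5 adjusted over the list alone; median 0.25, adjusted p = 0.996). The core histone list fell, as did the DNA replication list, with 24 of 38 genes lower and 0 higher (24 and 0 adjusted over the list alone; median -3.45). Their medians were nearer to 0 on log2(FPKM + 1) (-2.94 and -1.33) and after quantile normalization (-2.73 and -0.988). The core histone list had adjusted p = 2.8e-112 by camera and adjusted p = 0.152 with an estimated correlation, and the DNA replication list had adjusted p = 5.09e-17 by camera and adjusted p = 0.235 with an estimated correlation. A replication protein A subunit gene, TraesCS4B02G246900 on chromosome 4B, whose product binds single-stranded DNA during replication, went from 11.9 ± 0.751 to 0.381 ± 0.233 FPKM (log2 fold change -4.70, SE 0.42, adjusted p = 0.000804). Its counterpart on 4D, TraesCS4D02G246300, went from 9.24 ± 1.33 to 0.271 ± 0.271 FPKM. Meiosis genes were lower in 63 of 127 cases and higher in 0 (67 and 0 adjusted over the list alone; median -1.25, or -0.653 on log2(FPKM + 1) and -0.395 after quantile normalization). The meiosis list had adjusted p = 8.62e-12 by camera, and adjusted p = 0.152 with an estimated correlation. One of them, Meiosis 5 (TraesCS3A02G314100), went from 73.0 ± 19.3 to 11.2 ± 3.05 FPKM. Among genes with at least 5 FPKM, 16 meiosis genes remained and the list no longer passed (median -0.37). Cytosolic ribosomal protein genes fell as a list by less, with 14 of 137 lower and 0 higher (15 and 0 adjusted over the list alone; median -0.76). The ribosomal protein list had adjusted p = 5.05e-15 by camera, and adjusted p = 0.581 with an estimated correlation. Heat shock protein genes were lower in 7 of 48 cases and higher in 0 (7 and 0 adjusted over the list alone; median -0.45), among them HSP70 TraesCS1D02G284000, from 13.6 ± 3.74 to 2.39 ± 0.377 FPKM. The heat shock list had adjusted p = 0.00647 by camera, and adjusted p = 0.282 with an estimated correlation. Histone genes are near-identical copies, so the value of any single one is uncertain; summed over 474 core histone genes, CPM (counts scaled to library size) were 5577 to 7697 in the F1 libraries and 1430 to 1491 in the F5 libraries.

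Sugar genes moved in both directions. Among 22 sucrose synthase genes, which cleave sucrose, 7 were higher and 5 were lower in F5 (8 and 5 adjusted over the list alone) and the list did not pass (adjusted p = 0.519). TraesCS7A02G040900 (chromosome 7A, positions 19002179 to 19007777) went from 1.96 ± 0.891 to 33.0 ± 12.8 FPKM (log2 fold change 4.33, SE 0.498, adjusted p = 0.00169). TraesCS2D02G175600 (chromosome 2D, positions 119066592 to 119072213), abundant in Anther at 183 FPKM, went the other way, from 10.5 ± 6.92 to 0.127 ± 0.0781 FPKM (log2 fold change -6.05, SE 0.645, adjusted p = 0.00133). The 72 SWEET or sucrose transporter genes split into 11 higher and 13 lower (11 and 13 adjusted over the list alone; adjusted p = 0.996), and the SWEET genes TraesCS7B02G160000 and TraesCS7D02G263100 fell from 7.25 ± 4.53 and 6.95 ± 4.21 FPKM to 0.0112 ± 0.00985 and 0.017 ± 0.0177 FPKM. Invertase genes, recognised by their annotated beta-fructofuranosidase activity, were higher in 12 of 26 cases and lower in 9 (12 and 9 adjusted over the list alone; median 0.23, or 0.461 without F1 replicate 3, 0.44 without F5 replicate 3, 2.00 on log2(FPKM + 1) and 2.17 after quantile normalization). The invertase list had adjusted p = 0.000617 by camera, and adjusted p = 0.282 with an estimated correlation. TraesCS6A02G023100 rose from 0.247 ± 0.143 to 14.2 ± 4.56 FPKM, and TraesCS2D02G293200 fell from 16.8 ± 6.91 to 0.0796 ± 0.0364 FPKM.

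Several fructan and starch genes were lower in F5. Of 5 fructosyltransferase or fructan exohydrolase genes 3 were lower and 2 higher (3 and 2 adjusted over the list alone; median -4.10), a call that limma on log2(FPKM + 0.1) or log2(FPKM + 1) did not give. The fructosyltransferase list had adjusted p = 3.49e-05 by camera, and adjusted p = 0.152 with an estimated correlation. Starch synthesis genes were lower in 14 of 37 cases and higher in 3 (14 and 3 adjusted over the list alone). The list was called lower although its median was 0.05, as its mean was -0.73; on log2(FPKM + 1) the median was -0.195 and after quantile normalization -0.134. The starch synthesis list had adjusted p = 0.0471 by camera, and adjusted p = 0.666 with an estimated correlation. That call did not hold under median-of-ratios scaling, among genes with at least 5 FPKM, with limma on log2(FPKM + 0.1) or log2(FPKM + 1), or without F1 replicate 1 (median 0.0646), F5 replicate 2 (0.00419) or F5 replicate 3 (0.0778). The median was -0.0311 without F1 replicate 2, -0.00171 without F1 replicate 3 and -0.05 without F5 replicate 1. The glucose-1-phosphate adenylyltransferase gene TraesCS1D02G427400, for the first committed step of starch synthesis, went from 59.5 ± 4.50 to 4.54 ± 1.66 FPKM, and the starch synthase gene TraesCS7D02G190100 from 6.39 ± 0.854 to 0.512 ± 0.263 FPKM. Starch degradation genes showed 5 higher and 6 lower of 36 (5 and 6 adjusted over the list alone; adjusted p = 0.921), and the alpha-amylase gene TraesCS7A02G383900 went from 6.02 ± 1.97 to 0.158 ± 0.0525 FPKM. Trehalose-phosphate synthase or phosphatase genes gave 13 higher and 8 lower of 58 (13 and 8 adjusted over the list alone; adjusted p = 0.523), sucrose-phosphate synthase or phosphatase genes 1 and 4 of 21 (1 and 4 adjusted over the list alone; adjusted p = 0.745), and hexokinase or fructokinase genes 0 and 2 of 26 (0 and 2 adjusted over the list alone; adjusted p = 0.922).

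**Figure D2:**
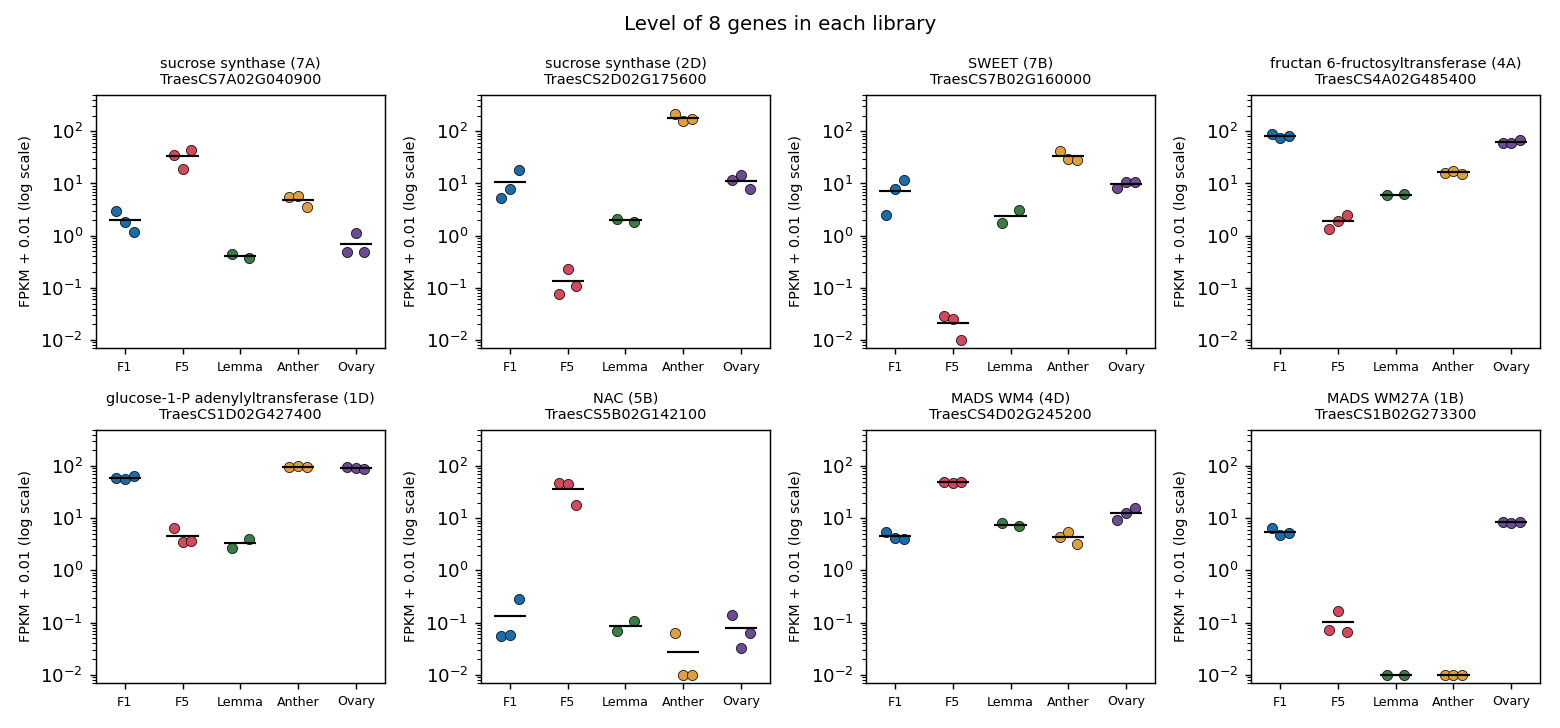
FPKM + 0.01 (log scale) of 8 genes in each of the 14 libraries; points are libraries and lines are group means. The sucrose synthase gene on 7A averages 33.0 FPKM in F5 and 1.96 in F1, and the one on 2D 0.127 and 10.5.

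Of the hormone lists, jasmonate synthesis and cytokinin metabolism were called higher in F5 and gibberellin oxidase lower, calls lost with an estimated correlation (adjusted p = 0.414, 0.235 and 0.428). Jasmonate synthesis genes were higher in F5 in 13 of 31 cases and lower in 1 (15 and 1 adjusted over the list alone; median 1.19, or 0.216 on log2(FPKM + 1) and 0.462 after quantile normalization), including the lipoxygenase gene TraesCS4B02G037900 with a log2 fold change of 2.30. The jasmonate list had adjusted p = 9.31e-05 by camera, and adjusted p = 0.414 with an estimated correlation. Cytokinin metabolism genes rose in 19 of 57 cases and fell in 11 (19 and 11 adjusted over the list alone; median 0.63, or 0.965 without F1 replicate 2). The cytokinin list had adjusted p = 0.0125 by camera, and adjusted p = 0.235 with an estimated correlation. One that fell, TraesCS1B02G471300, encodes a cytokinin riboside 5'-monophosphate phosphoribohydrolase, which releases active cytokinin, and went from 6.83 ± 3.43 to 0.272 ± 0.177 FPKM. Gibberellin oxidase genes were lower in 8 of 19 cases and higher in 2 (8 and 2 adjusted over the list alone; median -1.61, or -1.26 on log2(FPKM + 1) and -1 after quantile normalization), a call lost without F1 replicate 2 (median -1.29), F1 replicate 3 (-1.56) or F5 replicate 3 (-1.37), and with limma on log2(FPKM + 0.1) or log2(FPKM + 1). The gibberellin oxidase list had adjusted p = 0.0426 by camera, and adjusted p = 0.428 with an estimated correlation. GA2ox-D6 (TraesCS2D02G375300), of a family that inactivates gibberellin, went from 5.53 ± 0.844 to 0.301 ± 0.123 FPKM, and the gibberellin receptor gene GID1 (TraesCS1B02G265900) from 10.8 ± 3.29 to 26.7 ± 4.31 FPKM. Auxin response factor genes were lower in 18 of 67 cases and higher in 5 (20 and 5 adjusted over the list alone) without passing as a list (adjusted p = 0.0521), and TraesCS5B02G039800 went from 12.4 ± 1.52 to 2.18 ± 0.0656 FPKM. The auxin efflux carrier gene TraesCS7A02G190600 went from 6.82 ± 0.642 to 0.759 ± 0.204 FPKM, in an auxin transport and synthesis list with 6 higher and 7 lower of 39 (6 and 7 adjusted over the list alone; adjusted p = 0.921).

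The lignin synthesis list and the cuticle and wax list were called higher in F5, calls lost with an estimated correlation (adjusted p = 0.0927 and 0.428). The lignin synthesis list rose, with adjusted p = 1.23e-18 by camera, and adjusted p = 0.0927 with an estimated correlation. Among the genes that rose were laccases, which polymerise lignin precursors. TraesCS1B02G292600 went from 0.0911 ± 0.0991 to 7.65 ± 3.78 FPKM (log2 fold change 6.64, SE 0.861, adjusted p = 0.00249) and TraesCS1B02G293100 from 0.896 ± 0.425 to 14.0 ± 4.06 FPKM. Cuticle and wax genes rose in 40 of 104 cases and fell in 8 (43 and 14 adjusted over the list alone; median 1.23, or 0.816 on log2(FPKM + 1) and 0.985 after quantile normalization). The cuticle and wax list had adjusted p = 0.000162 by camera, and adjusted p = 0.428 with an estimated correlation. Cellulose synthase genes rose in 21 of 65 cases and fell in 8 (24 and 9 adjusted over the list alone; median 0.71), a call lost without F5 replicate 1 (median 0.169) or F5 replicate 3 (0.466). The median was 0.0911 without F1 replicate 1 and 0.227 without F5 replicate 2. The median level of the same list, as log2(CPM + 1), was nevertheless lower in F5 (2.67 to 2.82) than in F1 (2.85 to 3.32). The cellulose synthase list had adjusted p = 0.0277 by camera, and adjusted p = 0.376 with an estimated correlation. A xyloglucan endotransglucosylase/hydrolase gene, TraesCS3D02G093900, whose product remodels the wall, went from 0.0925 ± 0.076 to 16.4 ± 1.02 FPKM (log2 fold change 7.65, SE 0.446, adjusted p = 0.000288). The expansin list was split, 11 higher and 7 lower of 30 (12 and 8 adjusted over the list alone; adjusted p = 0.361). Within it TraesCS3B02G376800 rose from 5.20 ± 1.03 to 33.5 ± 13.0 FPKM, and TraesCS7D02G284000, at 182 FPKM in Anther, had no counts in F5 and was at least 914-fold lower there than in F1.

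The photosystem and Calvin cycle lists were also called higher in F5, though most of their members did not pass and the calls were lost with an estimated correlation (adjusted p = 0.65 and 0.634). Photosystem and light harvesting genes rose in 49 of 294 cases and fell in 1 (41 and 1 adjusted over the list alone; median 0.79), and Calvin cycle genes rose in 17 of 40 cases and fell in 0 (23 and 0 adjusted over the list alone; median 1.10, or 0.949 on log2(FPKM + 1) and 0.444 after quantile normalization). The photosystem list had adjusted p = 4.78e-11 by camera and adjusted p = 0.65 with an estimated correlation, and the Calvin cycle list had adjusted p = 1.83e-06 by camera and adjusted p = 0.634 with an estimated correlation. The chlorophyll a-b binding protein gene TraesCS6D02G088800 went from 5.99 ± 5.44 to 51.9 ± 13.3 FPKM. Beside these lists, genes enriched in Lemma took 38.4 ± 1.55% of the counts in F5 and 26.6 ± 6.15% in F1 (SD, n = 3). Senescence and autophagy genes rose in 11 of 84 cases and fell in 0 (11 and 0 adjusted over the list alone; median 0.33, or 0.0422 on log2(FPKM + 1) and 0.188 after quantile normalization), a call absent among genes with at least 5 FPKM. The senescence and autophagy list had adjusted p = 0.00283 by camera, and adjusted p = 0.65 with an estimated correlation. Organelle-encoded or ribosomal RNA genes rose in 142 of 1674 cases and fell in 110 (130 and 101 adjusted over the list alone; median 0.32, or 0.49 without F1 replicate 1, 0.0586 on log2(FPKM + 1) and 0.215 after quantile normalization), a call lost without F1 replicate 2 (median 0.27), F1 replicate 3 (0.255) or F5 replicate 1 (0.0557), and among genes with at least 5 FPKM. Ribosomal RNA took 0.6081 to 0.7429% of counts in F1 and 0.6052 to 1.614% in F5. The organelle list had adjusted p = 0.0385 by camera, and adjusted p = 0.871 with an estimated correlation.

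The NAC domain and MADS-box lists were called in opposite directions, calls lost with an estimated correlation (adjusted p = 0.235 each). Both lists hold only genes matched by name or description, which 15.2% of genes have, so they do not stand for the whole families. NAC domain genes rose in 6 of 12 cases and fell in 0 (6 and 0 adjusted over the list alone; median 1.01). The NAC list had adjusted p = 0.000105 by camera, and adjusted p = 0.235 with an estimated correlation. TraesCS5B02G142100 (log2 fold change 8.49, SE 0.782, adjusted p = 0.00086) and TraesCS5A02G143200 (from 0.178 ± 0.0579 to 29.0 ± 11.4 FPKM) averaged at most 0.178 FPKM in F1, Lemma, Anther and Ovary. MADS-box genes, which specify floral organs, fell in 12 of 26 cases and rose in 3 (12 and 3 adjusted over the list alone; median -1.55, or -1.02 without F5 replicate 3). The MADS-box list had adjusted p = 0.00109 by camera, and adjusted p = 0.235 with an estimated correlation. WM27A (TraesCS1B02G273300), found in Ovary at 8.35 ± 0.264 FPKM and without counts in Lemma and Anther, went from 5.44 ± 0.835 to 0.093 ± 0.0579 FPKM. WM4 (TraesCS4D02G245200) went from 4.47 ± 0.740 to 49.2 ± 0.836 FPKM (log2 fold change 3.72, SE 0.183, adjusted p = 0.000218), above its level in any of the organs.

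Several genes that fell far were abundant in anthers and uneven among the F1 libraries. The profilin gene TraesCS3B02G311200, for an actin-binding protein, averaged 736 FPKM in Anther and went from 37.1 ± 36.6 FPKM in F1 to 0.0395 ± 0.0386 in F5 (adjusted p = 0.00401). The defensin gene TraesCS2B02G062100 averaged 221 FPKM in Anther and 12.6 ± 12.9 in F1, had no counts in F5 and was at least 900-fold lower there. An actin-depolymerizing factor 11 gene, TraesCS6D02G229200, went from 14.3 ± 14.0 to 0.0383 ± 0.0663 FPKM.

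**Figure D3:**
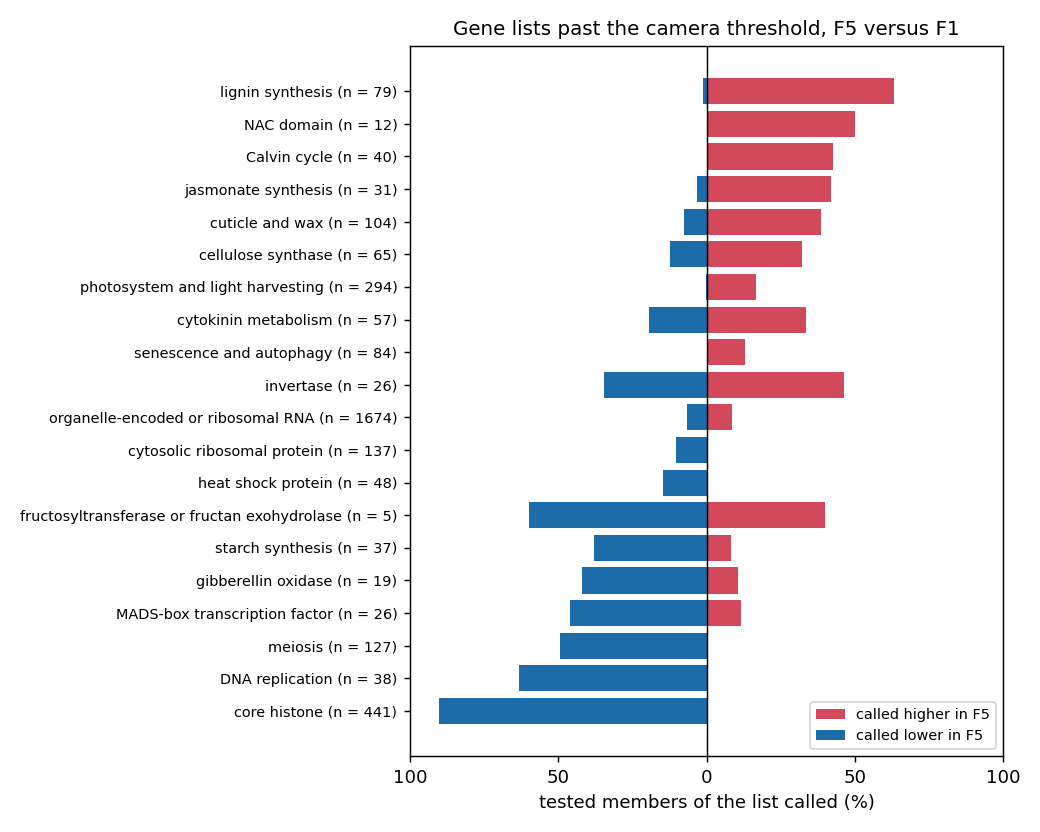
Percentage of tested members called higher (right) or lower (left) in F5 than in F1, for the 20 gene lists that passed the camera test with its preset correlation; n is the number of tested members. All 20 calls are lost with an estimated correlation. Core histone genes are lower in 398 of 441 cases and lignin synthesis genes higher in 50 of 79.

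The organ comparisons address what the lemma, anther and ovary of a fertile floret each express. Of 76348 tested genes, 12830 were higher in Lemma than in both other organs, 10906 in Anther and 7295 in Ovary. Lemma was marked by the small subunit gene of ribulose bisphosphate carboxylase TraesCS2D02G065500, at 195 ± 30.4 FPKM (SD, n = 2) against 0.182 ± 0.315 in Anther, all of it from replicate 2, and no counts in Ovary, at least 10492-fold lower. Anther was marked by the beta-amylase gene TraesCS5A02G513200, whose product releases maltose from starch, at 442 ± 60.2 FPKM (SD, n = 3) against 1.87 ± 0.327 in Lemma and 4.36 ± 2.27 in Ovary. Ovary was marked by the defensin gene TraesCS1D02G052900, for a small antimicrobial peptide, at 181 ± 38.3 FPKM against 0.346 ± 0.269 in Lemma and 0.0606 ± 0.0616 in Anther.

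By edgeR, Anther against Lemma gave 39589 changed genes (51.9%), with 19240 higher and 20349 lower in Anther. Ovary against Lemma gave 32619 (42.7%), 15550 higher and 17069 lower in Ovary, and Anther against Ovary gave 33222 (43.5%), 16687 higher and 16535 lower in Anther (quasi-likelihood test, Benjamini-Hochberg). The counts fell to 17700, 14568 and 15334 among genes with at least 5 FPKM and to 23163, 20183 and 18811 after quantile normalization, in the same order. Limma on log2(FPKM + 1) was the test planned for these comparisons before counts were found. It gave 23484, 23579 and 20112, and limma on log2(FPKM + 0.1) 30677, 31299 and 27402, so both put Ovary against Lemma above Anther against Lemma. Limma on log2(FPKM + 1) also turned the balance in Anther against Lemma (12187 higher and 11297 lower), Ovary against Lemma (14823 and 8756) and Anther against Ovary (7870 and 12242). It moved the median log2 fold change of all genes to 0.17, 0.44 and -0.27.

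Ribosomal RNA also differed between organs, at 3.578 to 4.082% of counts in Anther, 1.982 to 2.015% in Lemma and 0.6947 to 3.197% in Ovary. The organelle-encoded or ribosomal RNA list of 1828 genes was called lower in Anther than in Lemma (234 higher and 565 lower, 228 and 559 adjusted over the list alone), lower in Ovary than in Lemma (87 and 555, 86 and 552 adjusted over the list alone) and higher in Anther than in Ovary (568 and 180, 565 and 179 adjusted over the list alone). By camera these had adjusted p = 0.0233, 1.07e-06 and 0.0166, and with an estimated correlation adjusted p = 0.772, 0.624 and 0.654. In Anther against Lemma the median was 0.52 although the mean was -0.52, and the call was lost with either limma test, the replicate block or at least 5 FPKM. It was also lost without Lemma replicate 1 or 3, Anther replicate 1, 2 or 3, or Ovary replicate 2 or 3 (medians 0.346 to 0.59). In Ovary against Lemma the median of -0.555 became -0.23 without Ovary replicate 2 and -1.04 without Ovary replicate 3, or -0.11 on log2(FPKM + 1) and -0.251 after quantile normalization. In Anther against Ovary the median of 0.751 became 1.29 without Ovary replicate 3 and 0.394 on log2(FPKM + 1). That call was not given among genes with at least 5 FPKM.

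In Anther against Lemma, light harvesting fell almost throughout: 285 of 308 photosystem and light harvesting genes were lower and 6 higher in Anther (288 and 6 adjusted over the list alone; median -4.93, adjusted p = 5.57e-61), as were 34 of 40 Calvin cycle genes with 1 higher (34 and 1 adjusted over the list alone; median -7.35, adjusted p = 1.62e-52). These 2 of the 14 passing lists also passed with an estimated correlation (adjusted p = 0.0413 for each). Lignin synthesis genes were lower in 53 of 77 cases and higher in 9 (53 and 10 adjusted over the list alone; median -3.96, or -1.77 on log2(FPKM + 1) and -1.93 after quantile normalization). The lignin list had adjusted p = 7.92e-06 by camera, and adjusted p = 0.291 with an estimated correlation. Pathogenesis-related genes were lower in 49 of 66 cases and higher in 3 (50 and 4 adjusted over the list alone; median -3.42, or -3.33 with genes at 0 set to their bound, -1.46 on log2(FPKM + 1) and -1.60 after quantile normalization). The pathogenesis-related list had adjusted p = 0.000226 by camera, and adjusted p = 0.597 with an estimated correlation. Core histone genes were higher in 249 of 456 cases and lower in 14 (249 and 14 adjusted over the list alone; median 1.80, or 1.73 at the bound, 2.93 without Lemma replicate 3, 0.505 on log2(FPKM + 1) and 0.457 after quantile normalization). Expansin genes were higher in 20 of 33 cases and lower in 5 (20 and 6 adjusted over the list alone; median 3.35, or 3.03 at the bound, 1.21 on log2(FPKM + 1) and 1.18 after quantile normalization). The expansin call was not given by limma on log2(FPKM + 0.1) or log2(FPKM + 1), with the replicate block or among genes with at least 5 FPKM, nor without Lemma replicate 1 (median 3.09), Lemma replicate 3 (3.02) or Anther replicate 3 (3.33). The core histone list had adjusted p = 5.13e-07 by camera and adjusted p = 0.597 with an estimated correlation, and the expansin list had adjusted p = 0.026 by camera and adjusted p = 0.291 with an estimated correlation. Anther expressed genes with no counts in Lemma or Ovary: the trehalose 6-phosphate phosphatase gene TraesCS2B02G430700 stood at 48.4 ± 4.76 FPKM, at least 6341-fold above Lemma and at least 9012-fold above Ovary, and the phosphatidylinositol 4-phosphate 5-kinase gene TraesCS4B02G133100 at 19.2 ± 0.822 FPKM. Beta-expansin 2 (TraesCS1D02G211500), of a family that loosens cell walls, reached 140 ± 12.4 FPKM.

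In Ovary against Lemma, the core histone, DNA replication and meiosis lists were called higher and the photosystem list lower in Ovary, calls lost with an estimated correlation (adjusted p = 0.0711, 0.109, 0.0711 and 0.0711). Cyclin or cyclin-dependent kinase genes did not pass as a list (11 higher and 7 lower of 30, 11 and 7 adjusted over the list alone; adjusted p = 0.472). Core histone genes were higher in 432 of 456 cases and lower in 1 (433 and 1 adjusted over the list alone; median 6.89, or 6.73 at the bound, 4.56 on log2(FPKM + 1) and 4.42 after quantile normalization). The core histone list had adjusted p = 1.05e-65 by camera, and adjusted p = 0.0711 with an estimated correlation. DNA replication genes were higher in 30 of 40 cases and lower in 0 (31 and 0 adjusted over the list alone; median 3.92), and meiosis genes in 82 of 128 with 1 lower (83 and 2 adjusted over the list alone; median 2.48). Their medians were 1.49 and 1.15 on log2(FPKM + 1) and 1.23 and 0.902 after quantile normalization. The DNA replication list had adjusted p = 5.59e-13 by camera and adjusted p = 0.109 with an estimated correlation, and the meiosis list had adjusted p = 1.49e-13 by camera and adjusted p = 0.0711 with an estimated correlation. Disrupted meiotic cDNA 1 (TraesCS5B02G131900), a recombinase gene, stood at 7.32 ± 0.450 FPKM in Ovary and 0.376 ± 0.269 in Lemma (log2 fold change 3.64, SE 0.50, adjusted p = 0.00051). MADS-box genes were higher in 13 of 26 cases and lower in 4 (13 and 4 adjusted over the list alone; median 0.92, or 1.72 without Lemma replicate 1 and 1.68 without Lemma replicate 3), among them TaAGL31 (TraesCS5D02G118200; log2 fold change 3.71, SE 0.407, adjusted p = 0.00015). That list call was not given by limma on log2(FPKM + 0.1) or log2(FPKM + 1) or with the replicate block, nor without Anther replicate 2 or 3 (median 0.924 each). The MADS-box list had adjusted p = 0.0121 by camera, and adjusted p = 0.529 with an estimated correlation. Photosystem and light harvesting genes were lower in 290 of 308 cases and higher in 2 (291 and 2 adjusted over the list alone; median -5.71). The photosystem list had adjusted p = 1.08e-66 by camera, and adjusted p = 0.0711 with an estimated correlation. SWEET or sucrose transporter genes were lower in 37 of 73 cases and higher in 7 (37 and 7 adjusted over the list alone; median -1.67, or -0.747 on log2(FPKM + 1) and -0.996 after quantile normalization), and the Lemma gene TraesCS6D02G367400 averaged 52.4 ± 34.6 FPKM against 0.0864 ± 0.081 in Ovary. The transporter list had adjusted p = 0.00133 by camera, and adjusted p = 0.137 with an estimated correlation. Invertase genes were lower in 15 of 26 cases and higher in 4 (16 and 4 adjusted over the list alone; median -2.13, or -1.04 on log2(FPKM + 1) and -1.22 after quantile normalization). The invertase list had adjusted p = 0.012 by camera, and adjusted p = 0.137 with an estimated correlation. Neither the transporter nor the invertase call was given among genes with at least 5 FPKM.

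In Anther against Ovary, the core histone and cytosolic ribosomal protein lists were called lower in Anther, the latter with most of its members not called. Both calls were lost with an estimated correlation (adjusted p = 0.505 and 0.604). Core histone genes were lower in Anther in 415 of 456 cases and higher in 18 (416 and 18 adjusted over the list alone; median -4.96, or -4.95 at the bound), and cytosolic ribosomal protein genes in 37 of 138 with 6 higher (37 and 6 adjusted over the list alone; median -0.81, or -1.17 on log2(FPKM + 1) and -1.28 after quantile normalization). The core histone list had adjusted p = 1.33e-49 by camera and adjusted p = 0.505 with an estimated correlation, and the ribosomal protein list had adjusted p = 5.8e-09 by camera and adjusted p = 0.604 with an estimated correlation. Auxin response factor genes were lower in 29 of 67 cases and higher in 4 (29 and 5 adjusted over the list alone; median -0.84), with TraesCS6D02G127600 at 0.409 ± 0.534 FPKM in Anther and 16.3 ± 2.78 in Ovary. The auxin response factor list had adjusted p = 0.000299 by camera, and adjusted p = 0.505 with an estimated correlation. Cuticle and wax genes were lower in 46 of 97 cases and higher in 10 (47 and 10 adjusted over the list alone; median -2.07, or -1.34 at the bound, -1.04 on log2(FPKM + 1) and -0.909 after quantile normalization), with the 3-ketoacyl-CoA synthase gene TraesCS5D02G316100 at 0.141 ± 0.194 against 30.4 ± 3.77 FPKM. The cuticle and wax list had adjusted p = 0.00264 by camera, and adjusted p = 0.535 with an estimated correlation, and its call was not given among genes with at least 5 FPKM. Sucrose-phosphate synthase or phosphatase genes were higher in Anther in 10 of 21 cases and lower in 3 (10 and 3 adjusted over the list alone; median 0.84). The sucrose-phosphate list had adjusted p = 0.00134 by camera, and adjusted p = 0.535 with an estimated correlation. The list includes genes annotated with sucrose synthase activity, among them TraesCS3D02G420300 at 183 ± 0.630 FPKM in Anther and 1.30 ± 0.151 in Ovary. Pollen genes were higher in 89 of 298 cases and lower in 45 (89 and 45 adjusted over the list alone; median 0.30, or 0.0442 on log2(FPKM + 1) and 0.244 after quantile normalization), a call lost with the replicate block and without Lemma replicate 1 (median 0.291) or Lemma replicate 3 (0.26). Many genes of the pollen list are for recognition of pollen. It took ontology terms only for genes without a name or description. The added lists for pollen development and for recognition of pollen also took them for named genes, so they are not parts of it. Neither added list passed by camera. Pollen development without recognition of pollen had 30 higher and 43 lower of 170 (30 and 44 adjusted over the list alone, adjusted p = 0.691). Recognition of pollen had 52 and 48 of 262 (43 and 45 adjusted over the list alone, adjusted p = 0.901). Which members carried the call of the pollen list was not tested. The pollen list had adjusted p = 0.03 by camera, and adjusted p = 0.505 with an estimated correlation. With an estimated correlation 0 of the 43 lists passed in Ovary against Lemma (9 at an unadjusted p under 0.05) and 0 in Anther against Ovary (3 at an unadjusted p under 0.05), where fry, with its other question, passed 31 and 35.

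Genes enriched in one organ were then followed in the florets, whose libraries took no part in defining them. Ovary-enriched genes were lower in F5 in 3517 of 6969 cases (50.5%) and higher in 395 (3676 and 422 adjusted over the list alone), with a median log2 fold change of -1.25. The ovary-enriched set had adjusted p = 2.81e-29 by camera, and adjusted p = 0.0616 with an estimated correlation. Anther-enriched genes were lower in 1960 of 7855 cases (25%) and higher in 434 (1993 and 439 adjusted over the list alone; median -0.53, or -0.267 among genes with at least 5 FPKM). The anther-enriched set had adjusted p = 8.41e-05 by camera, and adjusted p = 0.316 with an estimated correlation. Lemma-enriched genes were higher in 2638 of 12213 cases (21.6%) and lower in 440 (2668 and 453 adjusted over the list alone; median 0.58). The lemma-enriched set had adjusted p = 7.3e-13 by camera, and adjusted p = 0.264 with an estimated correlation. Of 43184 tested genes in none of these sets, 3865 were higher and 3709 lower. Ovary-enriched genes took 8.62 ± 1.15% of counts in F1 and 4.46 ± 0.354% in F5 (SD, n = 3), and anther-enriched genes 7.09 ± 1.49% and 5.16 ± 0.147%. The F1 libraries differed among themselves: anther-enriched genes took 5.73, 6.85 and 8.68% of their counts and lemma-enriched genes 33.1, 25.7 and 20.9%.

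**Figure D4:**
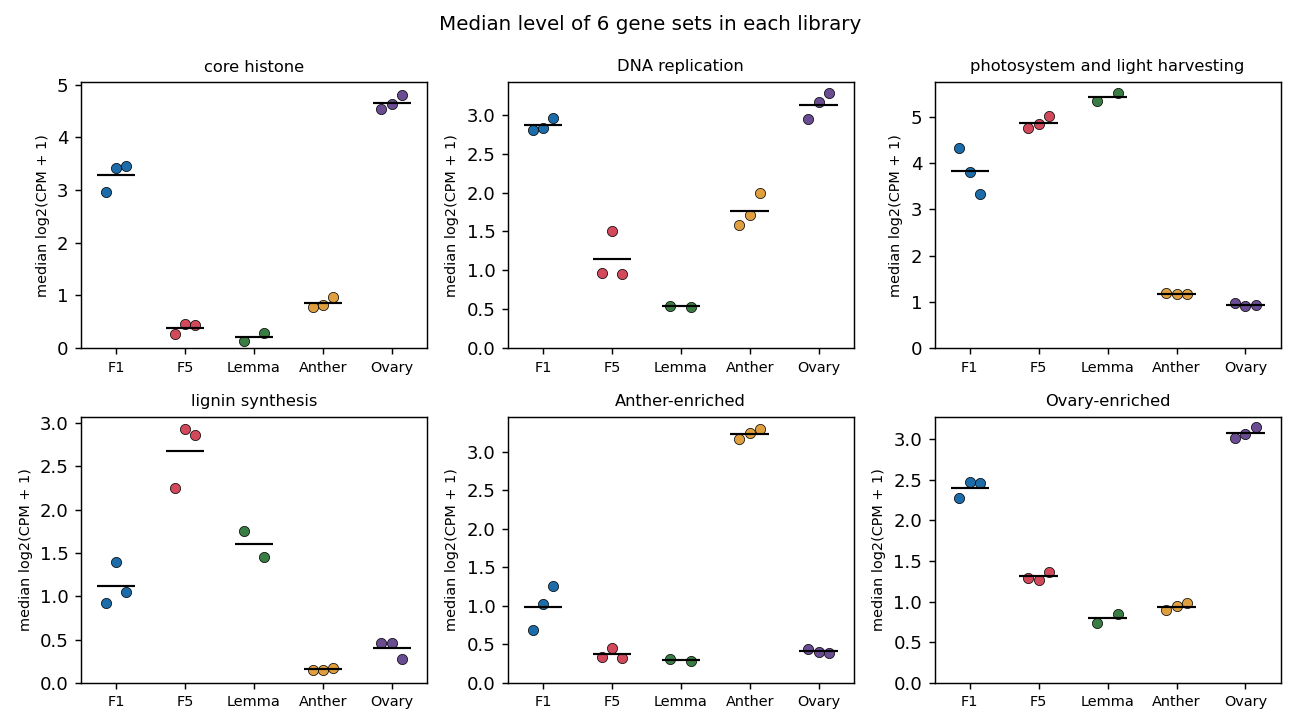
Median log2(CPM + 1) of 6 gene sets (4 gene lists, the anther-enriched and the ovary-enriched genes) in each of the 14 libraries; points are libraries and lines are group means. Ovary-enriched genes lie between 2.28 and 2.47 in F1, between 1.27 and 1.37 in F5 and between 3.01 and 3.15 in Ovary.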

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

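The DESeq2 Wald test, and limma on log2(FPKM + 1) as an alternative, were chosen after the data were seen, and the other alternatives before; for the organ comparisons limma on log2(FPKM + 1) was the planned test, and edgeR was the choice made after the data were seen. No list or named gene was called in the opposite direction. With at least 5 FPKM, fewer genes were tested and 5244 genes were called in F5 against F1, 17700 in Anther against Lemma, 14568 in Ovary against Lemma and 15334 in Anther against Ovary; organ-enriched genes numbered 15052 (Lemma 6123, Anther 5368, Ovary 3561), and 7 lists passed in Anther against Lemma and 10 in Anther against Ovary. Quantile normalization gave 8000, 23163, 20183 and 18811 called genes. Limma on log2(FPKM + 1) gave 8592 in F5 against F1, 23484 in Anther against Lemma and 20112 in Anther against Ovary. It also gave 7543 lemma-enriched and 6426 anther-enriched genes, and limma on log2(FPKM + 0.1) gave 8461 lemma-enriched genes. Both limma tests covered fewer genes than edgeR (48638 against 70221 in the florets). On those 48638 genes, 12350 were called in F5 against F1 with the pseudocount of 0.1 and 8592 with that of 1. In Ovary against Lemma these were 31299 and 23579 of the same 55974 genes. The pseudocount therefore accounts for part of the smaller numbers with log2(FPKM + 1), and other causes were not tested. These limma tests moved the median log2 fold change of all genes, for log2(FPKM + 1) to -0.17 in F5 against F1, 0.17 in Anther against Lemma, 0.44 in Ovary against Lemma and -0.27 in Anther against Ovary. They used the deposited FPKM, which lack TMM scaling. The TMM factors were 0.779 and 0.792 in Lemma, 0.942 to 0.951 in Anther and 1.2 to 1.28 in Ovary. In the florets they were 1.07 to 1.17 in F1 and 0.889 to 0.906 in F5. Leaving such factors out raises the group with the larger ones, which is the direction of each of these shifts. Several list medians were nearer to 0 on log2(FPKM + 1) and after its quantile normalization than by edgeR, with fewer genes tested. The pseudocount is part of this, as medians of the same members differed between the limma tests. For 11 gibberellin oxidase genes in F5 against F1 the median was -1.87 on log2(FPKM + 0.1) and -1.26 on log2(FPKM + 1). For 27 expansin genes in Anther against Lemma it was 2.33 and 1.21. Other causes were not tested. With log2(FPKM + 0.1), 21106 genes were higher and 10193 lower in Ovary against Lemma, the opposite balance to the 15550 and 17069 by edgeR. With an estimated correlation 0 of the 3 organ-enriched sets passed in F5 against F1 (medians 0.58, -0.53 and -1.25 for Lemma, Anther and Ovary), and 0 lists passed in F5 against F1, 2 in Anther against Lemma, 0 in Ovary against Lemma and 0 in Anther against Ovary, where 9, 3, 9 and 3 had an unadjusted p under 0.05 and fry passed 24, 36, 31 and 35. Leaving out 1 library gave 12367 (without F5 replicate 1) to 20310 (without F1 replicate 1) genes in F5 against F1, 35939 to 39845 in Anther against Lemma, 28557 to 32376 in Ovary against Lemma, 30660 to 33229 in Anther against Ovary, and 27249 to 30117 organ-enriched genes. The numbers of passing lists ranged over 17 to 21, 11 to 16, 13 to 16 and 11 to 17, and the medians of the lemma-, anther- and ovary-enriched sets over 0.45 to 0.79, -0.73 to -0.44 and -1.39 to -1.21. With Lemma at 1 library, that library is assumed to vary like the other organs. The replicate numbers give no sign of pairing: correlations of the deviations of libraries from their group means, between libraries of the same number in both groups compared, lay between -0.18 and 0.061. With the replicate number as a block, 13834, 33322, 27003 and 28746 genes were called. With at least 5 FPKM only 60 of the 85 genes named for F5 against F1 were tested. Of the 85, 74 kept their call under every alternative in which they were tested. The calls of the ribulose bisphosphate carboxylase genes TraesCS2D02G065500 and TraesCS2B02G079400 and of TraesCS4D02G109500 were among the 11 that did not. In Anther against Lemma 42 of 42 kept theirs, in Ovary against Lemma 41 of 42 and in Anther against Ovary 44 of 45. At least 5 FPKM left 40 of these tested in Anther against Lemma, 41 in Ovary against Lemma and 45 in Anther against Ovary.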

Other observations

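The scaling tests, both tests on reads shared or moved between histone genes, the count of histone genes under 0.1 FPKM in an organ, the range between organs of anther-enriched genes and the 14 added lists were chosen after results or annotation had been seen; the tests of organ proportions, of the spread of anther-enriched genes and of other splits were set before their results were seen.

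Further gene groups differed between F5 and F1, by camera with its preset correlation. Of 323 genes with peroxidase activity, 110 were higher and 42 lower in F5 (114 and 43 adjusted over the list alone; median 0.87), and the peroxidase gene TraesCS1D02G096400 went from 0.199 ± 0.246 to 10.1 ± 5.39 FPKM. The peroxidase activity list had adjusted p = 1.24e-06 by camera, and adjusted p = 0.0673 with an estimated correlation. Of 56 genes annotated as responding to cytokinin, 19 were higher and 2 lower (19 and 2 adjusted over the list alone), and of 200 responding to auxin, 34 were higher and 6 lower (24 and 5 adjusted over the list alone). Both lists were added after the annotation was seen. The response to cytokinin list had adjusted p = 9.26e-05 by camera and adjusted p = 0.408 with an estimated correlation. The response to auxin list had adjusted p = 0.00439 by camera and adjusted p = 0.408 with an estimated correlation. The list of auxin response genes fixed beforehand (Aux/IAA, SAUR and GH3) did not pass in F5 against F1. Pollen development genes without the recognition of pollen terms were lower in 49 of 163 cases and higher in 5 (50 and 5 adjusted over the list alone; median -0.54). The pollen development list had adjusted p = 1.38e-05 by camera, and adjusted p = 0.0673 with an estimated correlation. The pollen list fixed beforehand did not pass by camera (15 higher and 50 lower of 259, 14 and 49 adjusted over the list alone, adjusted p = 0.074). Tapetum and exine genes did not pass either (7 higher and 7 lower of 45, 7 and 7 adjusted over the list alone, adjusted p = 0.922). Nor did recognition of pollen (15 and 25 of 212, 14 and 20 adjusted over the list alone, adjusted p = 0.759) or strictosidine synthase activity (4 and 7 of 28, 4 and 8 adjusted over the list alone, adjusted p = 0.759). Ovule and carpel genes were lower in 15 of 63 cases and higher in 4 (15 and 4 adjusted over the list alone; adjusted p = 0.0503). Of 137 pathways, 67 passed, 53 higher and 14 lower in F5, and 0 with an estimated correlation (22 at an unadjusted p under 0.05, 89 by fry). Mismatch repair was lower in 86 of 194 cases and higher in 4 (88 and 5 adjusted over the list alone), and alpha-linolenic acid metabolism, the route to jasmonate, higher in 62 of 215 and lower in 7 (68 and 10 adjusted over the list alone). The mismatch repair list had adjusted p = 5.03e-09 by camera and adjusted p = 0.272 with an estimated correlation, and the linolenic acid list had adjusted p = 1.58e-06 by camera and adjusted p = 0.272 with an estimated correlation.

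Core histone genes were lower in F5, with a median log2 fold change of -4.47. Scaling between libraries does not account for it, since the median nearest to 0 under 4 scalings was -2.73. These were TMM and median of ratios in edgeR, and deposited FPKM and quantile normalization in limma on log2(FPKM + 1). The limma values also differ in pseudocount and filter, so the range reflects more than scaling. Reads moving between near-identical copies would leave their sum as it was, but the log2 ratio of the summed CPM was -2.23, and -1.9 even between the highest F5 and the lowest F1 library. A further test of shared reads used the DNA replication genes. Their median of -3.45 has a 95% bootstrap interval of -3.95 to -0.999, which reaches past the bound of -1 set for that test. It cannot decide on shared reads in either direction, because it measures other genes than the histone copies. Another proportion of the profiled organs in F5 cannot be told apart from a change within them. A mixture needs values within the range of the organs, and 1.51% of the 398 called members (6 genes, interval 0.555 to 3.25%) had all F5 libraries below all organ libraries. However, 232 of the 398 had an organ library under 0.1 FPKM and so no room to fall below it, which leaves that share without weight. A difference between fertile and abortive florets stays open and was not tested.

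Lignin synthesis genes were higher in F5, with a median log2 fold change of 1.89. Scaling does not account for it, since the median nearest to 0 under the same 4 scalings was 1.34, again with another pseudocount and filter in the limma values. Of the 50 called members, 86% (43 genes, interval 73.3 to 94.2%) had all F5 libraries above all organ libraries. Other proportions of lemma, anther and ovary as profiled would not give such values, which argues against them as the whole cause for these 43 genes. These members were chosen as higher in F5 from 79 tested. The interval treats genes as independent, and Lemma has 2 libraries. Floret parts that were not profiled, and a difference between fertile and abortive florets, may each contribute and were not tested.

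Anther-enriched genes were lower in F5 and uneven among the F1 libraries. A smaller share of anther tissue in F5 cannot be told apart here from a change in anther expression. The interquartile range of their log2 fold changes was 2.08 (95% bootstrap interval 1.98 to 2.18), but that range decides nothing. These genes also took 3.61% of counts in Lemma and 6.27% in Ovary, and their smaller log2 fold change over the other organs had an interquartile range of 2.96, so a smaller share would lower them by unequal amounts. No biological explanation was tested.

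Other splits of the same 6 libraries into 3 and 3 were compared with the real one; with 10 splits no share under 0.05 is possible. In F5 against F1 the real split called 16958 genes and the highest other split 0 by edgeR (1 of 10 as large), and in Anther against Ovary 33222 and 0 (1 of 10). For lists with the preset correlation the real split passed 20 in F5 against F1 and the highest other split 19 (1 of 10 as large), and in Anther against Ovary 16 and 14 (1 of 10). For the organ-enriched sets the real split passed 3 and the highest other split 3 (7 of 10 as large). Each other split sets 2 libraries of one group and 1 of the other against the reverse. The difference between the real groups then counts as spread within each side, which by itself keeps genes from being called. The counts of 0 genes are therefore no baseline for the real split.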
